A study of Mus musculus with 3 samples.

How the data were processed

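Single-cell RNA sequencing was carried out on nephron progenitors, the self-renewing mesenchymal cells that give rise to every nephron, sorted from mouse kidneys at embryonic day 14.5 by green fluorescent protein made from the Six2 locus. Per the labels, kidneys of several litters were pooled into 3 tubes, the sort also excluded dead cells, debris and doublets, and the tubes were run in parallel on 1 chip of the 10x Chromium system (version 2 chemistry) with paired reads of 100 bases. The labels put all 3 samples in 1 group. The deposited values are counts, whole numbers of unique molecular identifiers (UMIs) per gene and cell, made by the authors with Cell Ranger 1.3.1 against mm10, per the submitters' processing notes. The authors deposited the same counts as a sparse matrix and as a text table, and all 27998 genes had equal values in both. The matrix joins the libraries and marks the library of each cell by a suffix of its barcode (1, 2 or 3), which is used here as the library's name. Which label belongs to which suffix is not given in the sources used here. A further filter before deposit is not given either.

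Cells needed at least 1000 detected genes and at most 10% mitochondrial UMIs, which kept 7898 of 7924 barcodes. Scrublet's method, run per library with an expected doublet share of 3%, called 38 cells (0.48%), which were left out. This share is far below the expected 3%, and how many doublets the caller missed was not tested. Doublets therefore have to be taken as still present, and removal of the 6% highest scores was added as an alternative. The kept cells numbered 3002, 2754 and 2104 in libraries 1, 2 and 3, with 50162210, 35110610 and 35447738 UMIs. A further 2 cells with over 1% haemoglobin UMIs (up to 28.6%) stayed out of the classes compared. Library-level totals correlated at 0.984 to 0.996 (Pearson's r of log2 CPM, counts scaled to a common library total, across genes, which are not independent replicates). The chi-square of counts over its degrees of freedom was 56.1 to 318 between libraries, far above sampling noise, so no library was a copy of another. Each library was 1 tube of several litters. In the tests below the library is a block, so p-values measure only how differences within a tube vary over these 3 tubes. That spread may be technical.

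Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 on log-normalised counts (10000 per cell) of the 1000 most variable genes, without mitochondrial genes, ribosomal genes and the genes of the lists named below, with 30 principal components, 20 neighbours and resolution 0.8. The comparisons, lists, cell type markers, the rule for named genes and most alternatives were fixed before the data were examined. The plan had no centring by library. Clusters then followed the libraries: 11 of 13 held over 90% of their cells from 1 library, with an adjusted Rand index of 0.378 between cluster and library. Log values were therefore centred per library, which the plan listed as an alternative, and 204 variable genes that correlated (absolute r above 0.1) with a cell cycle score were left out, leaving 796 clustering genes and an index of 0.003. This was decided after seeing the clusters and before any test of expression. There were 17 clusters, 7 of them of 1 cell each. Clusters 0, 1, 3, 4 and 6 were named uncommitted progenitors (markers Six2, Cited1, Meox1, Eya1, Crym, Osr1, Traf1, Rspo1). None of these markers was among the 10 leading genes of any of these clusters. In cluster 4 the committing marker Pax8 was at 36.6 ± 7.72 CPM (SD, n = 3), against 22.4 ± 3.55 in the other uncommitted clusters. Epcam, which encodes an epithelial adhesion molecule, was among the 10 leading genes of cluster 4, so its name as uncommitted is less sure. Cluster 5 was named committing (Wnt4, Pax8, Tmem100, Ccnd1, Fgf8, Bmper), although Fgf8 ran the other way, at 23.2 ± 6.31 CPM (SD, n = 3) in committing and 44.8 ± 6.47 in uncommitted cells. Cluster 9 was named early nephron (markers including Jag1, Lhx1, Pou3f3, Osr2, Dll1, Emx2, Irx1, Bcat1), with the ureteric marker Calb1 the first of its leading genes, and cluster 8 immune (Ptprc, Tyrobp, Fcer1g, C1qb, Lyz2, Cx3cr1). Cluster 2 had 2 committing markers, Fgf8 and Pax8, and no uncommitted one among its 10 leading genes, but Six2 was found in 88.2% of its cells and Wnt4 in 4.51%, so it was kept apart as the Fgf8-high cluster. The leading genes of cluster 6 were class II antigen genes (H2-Eb1, H2-Ab1, Cd74, H2-Aa, H2-DMa, H2-DMb1) and none of the uncommitted markers. It was named for its marker levels, with Six2 in 86.1%, Cited1 in 72.8% and Eya1 in 94.9% of its cells and Ptprc in 0.28%, Fcer1g in 1.7% and C1qb in 1.13%. Markers of podocytes, tubules, stroma, ureteric epithelium, endothelium, erythroid, neural, mural and muscle cells named no cluster.

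UMIs were summed per library and class and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05, two-sided) in R 4.3.3, with the library as a block because each library holds every class. The block rests on this shared tube. Classes with enough cells entered each fit: uncommitted, committing and immune cells for committing against uncommitted cells, and these with early nephron cells for early nephron against committing cells. The Fgf8-high cluster stayed out of both. The plan asked for 20 cells per class and library. The early nephron class had 15 to 18, so its comparison used a minimum of 10, a choice made after seeing the cells. A planned comparison of stroma-like cells was not run because no cluster could be named stroma. Cluster 7 had the stroma markers Col1a1 and Col3a1 among its leading genes, but held progenitor transcripts as well and stayed unnamed. Genes used for clustering were left out of counts of calls and of named genes, as were Xist and 4 Y genes (Ddx3y, Eif2s3y, Uty, Kdm5d). Uncommitted cells with at least 1 Xist UMI and none of the Y genes were called female, those with the reverse male, and their sums per library were compared in the same way. The named genes were, among genes past the threshold with at least 20 CPM in the higher class and the same direction in every library, the 8 with the largest increase and the 8 with the largest decrease (without unnamed gene models, mitochondrial and ribosomal genes), up to 4 members with the smallest p of each list past its test, and, between the sexes, the 10 genes with the smallest p. A few further genes that make up small counts were named after their values were seen and are marked so. Standard errors are the log2 fold change over the root of F. Gene positions are those of GENCODE's annotation of mm10, matched by identifier for 27645 of 27998 genes.

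The 20 gene lists were canonical Wnt targets, Notch pathway, FGF and ERK response, BMP and TGF-beta response, epithelial junctions and polarity, mesenchymal genes, guidance and migration, integrins and matrix, glycolysis, oxidative phosphorylation, S phase, G2 and M phase, immediate early and dissociation stress, Hox genes, progenitor regulators, Lin28 and Igf2bp growth genes, Hippo targets, p53 targets, retinoid pathway and cytosolic ribosomal proteins. They were tested with camera of limma 3.58.1 on voom values at an inter-gene correlation of 0.01, adjusted over 60 tests of 3 comparisons, and again with an estimated correlation and with fry. Cell cycle shares and co-detection of gene pairs were computed after thinning each cell to 7689 UMIs (the 5th percentile), which left out 392 cells: 328 uncommitted, 15 Fgf8-high, 5 committing, 3 early nephron and 20 immune, the rest without a class. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only.

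Each test was tested on simulated data with 200 changed genes. For committing against uncommitted cells (11154 genes simulated), edgeR recovered 86% of genes changed 2-fold and 94% of those changed 4-fold, with 2.7% false calls. For early nephron against committing cells (10412 genes) the shares were 56% and 69%, with 4.6% false calls, and between the sexes (12500 genes) they were 89% and 98%, with 5.1% false calls. In the simulations the classes were given in advance. The false calls for the 2 comparisons of classes therefore do not cover the step of drawing classes from the tested expression. The alternatives fixed in advance were DESeq2's size factors, DESeq2 1.42.0's Wald test, no low-count filter, no library block, each library left out, only the classes compared in the fit, 2000 variable genes, resolutions of 0.5 and 1.2, doublets kept, count splitting, sums thinned to equal totals, other cell filters and thinning depths, at least 2 UMIs to call a sex, and camera with an estimated correlation. Alternatives chosen after seeing the data were clustering as planned or with cycle genes kept, the 6% doublet filter, cluster 1 left out, the Fgf8-high cluster added to the uncommitted class, the early nephron class added to the fit, sums of the 2 compared classes thinned to equal totals, early nephron cells with a UMI of a ureteric marker (Wnt11, Ret, Wnt9b, Calb1, Wnt7b, Aqp2, Gata3, Krt19) left out, and clustering without 19 genes whose level correlated (absolute r above 0.05) with the number of A and T bases in the cell barcode. The Leiden, doublet and thinning steps used a fixed random seed.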

Results

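The libraries describe the nephron progenitor pool of the fetal mouse kidney cell by cell. Library 1 held 3002 kept cells at a median of 15895 UMIs and 4059.5 genes per cell, library 2 held 2754 cells at 11903.5 UMIs and 3875 genes, and library 3 held 2104 cells at 15789.5 UMIs and 4198.5 genes. Ribosomal protein genes took 25.6%, 13.9% and 21.9% of UMIs in libraries 1, 2 and 3, and immediate early genes, which respond within minutes to stimulation and to tissue dissociation, took 0.397%, 0.749% and 0.503%.

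Most sorted cells were uncommitted progenitors. They made up 74.2% ± 0.99 of kept cells (SD, n = 3; 5844 cells), and a Fgf8-high cluster made up a further 15.9% ± 0.617 (1242 cells). Committing progenitors, which carry Wnt4, the signal that starts the mesenchymal-to-epithelial transition, made up 5.58% ± 0.473 (437 cells). Early nephron cells, with the LIM homeobox gene Lhx1 as a marker, made up 0.619% ± 0.086 (48 cells), and immune cells 0.949% ± 0.174 (73 cells). The remaining 2.72% ± 0.45 (214 cells) had no class name. The sort for Six2-driven fluorescence sets these shares, so they describe the sorted cells and not the kidney. Values were centred per library before clustering, which can make class shares more alike between libraries. The SDs of these shares may therefore be too small. The transcription factor Six2, which keeps progenitors self-renewing, was at 140 ± 27.2 CPM (SD, n = 3) in uncommitted, 155 ± 38.2 in Fgf8-high, 94.5 ± 25.4 in committing, 65.9 ± 44 in early nephron and 12.3 ± 10.7 in immune cells. Cited1, a transcriptional co-regulator of the least committed progenitors, was at 191 ± 27 CPM in uncommitted and 54.4 ± 15.6 in committing cells. Wnt4 was at 1.9 ± 0.63 and 54.4 ± 19.2 CPM in the same classes. Lhx1 was at 0.95 ± 0.82 CPM in committing and 169 ± 33.9 in early nephron cells. These markers named the classes and are not results. Class depended on the cell barcode. Among cells with 10 or more A and T bases in the 16 of the barcode, 2.45% were committing and 90.1% uncommitted, against 6.28% and 71.8% with at most 6 such bases and 5.96% and 72% in between. With 19 barcode-linked genes left out of the clustering, the committing shares were 4.89%, 4.93% and 5.89% in the same order, the uncommitted class took 88.8% ± 0.477 and no Fgf8-high cluster separated.

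Whether commitment goes with changes beyond its markers was asked by comparing committing with uncommitted progenitors. Id2 (ENSMUSG00000020644, chromosome 12, 25093799 to 25097140) rose by 1.86 ± 0.06 on the log2 scale (SE), from 212 ± 5.13 to 770 ± 6.05 CPM (SD, n = 3), and Id1 by 1.52 ± 0.07, from 76.6 ± 12.8 to 214 ± 27.1 CPM. Both encode helix-loop-helix proteins that BMP signals induce and that block differentiation factors. Of Wnt target genes, Sp5 (ENSMUSG00000075304, chromosome 2, 70474923 to 70477729), a transcription factor directly induced by beta-catenin, went from 0.59 ± 0.23 to 10.7 ± 1.74 CPM, a log2 change of 4.18 ± 0.33, and Lef1, the nuclear partner of beta-catenin, from 0.59 ± 0.16 to 6.54 ± 1.02 CPM, a log2 change of 3.44 ± 0.38. Among the genes named by the rule, the largest decrease was that of Dcx (ENSMUSG00000031285, chromosome X, 143855842 to 143933311), which encodes the microtubule-binding protein doublecortin of migrating neurons and fell by 2.47 ± 0.16, from 38.9 ± 4.39 to 7.52 ± 3.53 CPM. Dcx also varied within the uncommitted class, at 12.8 ± 1.53 CPM in cluster 4 and 43.1 ± 4.4 in the other uncommitted clusters.

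Of 10542 genes tested, 2317 passed (edgeR, adjusted p under 0.05): 1212 were higher and 1105 lower in committing cells. The 8 largest increases after the filters were those of Tmem100 (2.81 ± 0.14), Lmcd1 (2.06 ± 0.14), Sct (2.03 ± 0.16), Id2, Fgf9 (1.53 ± 0.17), Bmper (1.52 ± 0.09), Wfdc2 (1.52 ± 0.09) and Id1. Tmem100 and Bmper are class markers and cannot count as results. Lmcd1 encodes a LIM-domain co-regulator, Sct the hormone secretin, Fgf9 a fibroblast growth factor that maintains progenitors, and Wfdc2 a protease inhibitor typical of epithelia. Bmper encodes a modulator of BMP ligands. Besides Dcx, the largest decreases were those of Efemp1 (-2.38 ± 0.21), a matrix glycoprotein, Colec12 (-2.33 ± 0.11), a scavenger receptor, and Slc40a1 (-2.32 ± 0.19), the iron exporter ferroportin. They were followed by Ifitm1 (-2.21 ± 0.11), an interferon-inducible membrane protein, and Stc1 (-2.20 ± 0.11), the hormone stanniocalcin. Lfng (-2.004 ± 0.20), which glycosylates Notch receptors, and Pgf (-1.86 ± 0.10), placental growth factor, completed the 8. Efemp1 and Colec12 varied within the uncommitted class too. They were at 7.72 ± 1.06 and 31.2 ± 11.6 CPM (SD, n = 3) in cluster 4, against 23.3 ± 6.14 and 85.7 ± 16.6 in the other uncommitted clusters. The edgeR adjusted p of these 16 genes lay between 2.01e-33 (Id2) and 5.87e-11 (Fgf9), each in the same direction in 3 of 3 libraries. Not all of them passed under other settings. With count splitting Lfng fell by 0.76 ± 0.29 (edgeR adjusted p = 0.0548). With every sum in the fit thinned to 206713 UMIs the edgeR adjusted p was 0.281 for Lfng, 0.0862 for Slc40a1 and 0.0947 for Stc1, and without the library block it was 0.174 for Sct and 0.0519 for Wfdc2. The classes were drawn from the same cells' expression. With UMIs split at random so that separate parts clustered and tested the cells, 1338 genes passed, 495 higher and 843 lower, and of 2028 earlier calls that could be tested 991 were kept. DESeq2's Wald test called 671 genes and a fit without the library block 497. Sums thinned to 206713 UMIs, the total of immune cells in library 2, gave 65 calls. With only the compared sums thinned, to the 2009982 UMIs of committing cells in library 2, there were 1154 calls, an alternative chosen after seeing the data, and all 16 genes passed. Without libraries 1, 2 and 3 there were 1320, 2481 and 1125 calls. Fgf9 and Id2 belong to the genes higher in cluster 1, called barcode-linked where genes are named here. Of these, the 85 at least doubled there had a summed level that followed the cell barcode. The link was not tested for single named genes. Of 271 genes higher in cluster 1 that were tested, 92 passed, 28 higher and 64 lower in committing cells. That class had fewer barcodes rich in A and T. The 19 genes left out of the clustering are another set, picked by their own correlation with the barcode. With barcode-linked genes left out of the clustering, 2091 genes passed, 1839 of them among 2313 earlier calls that were tested again.

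**Figure D1:**
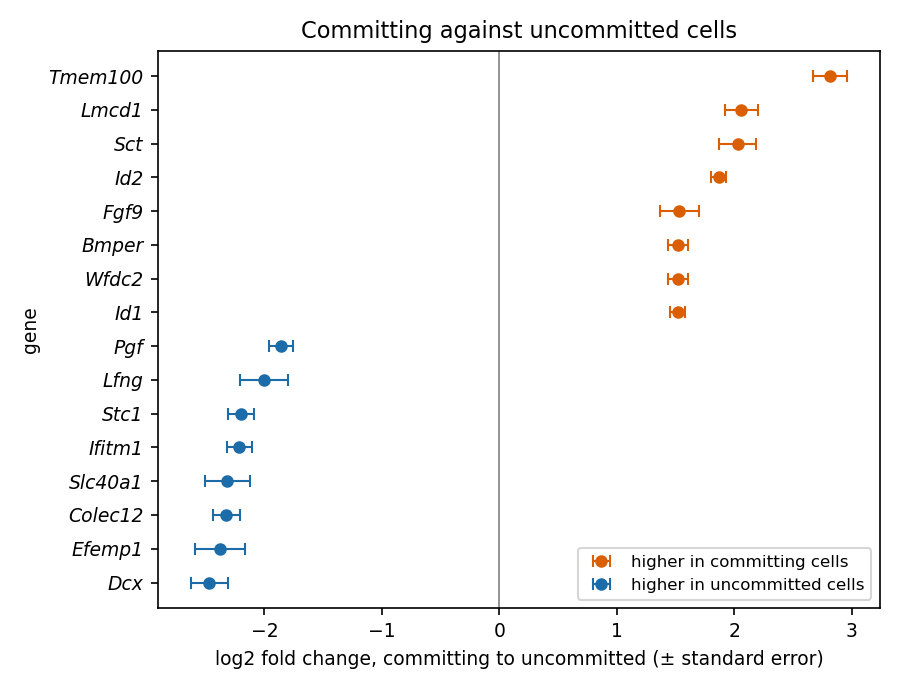
Log2 fold change (horizontal axis, log2 units, bars are standard errors) of the 16 named genes (vertical axis) between committing and uncommitted cells, summed per library (n = 3). Changes run from -2.47 for Dcx to 2.81 for Tmem100, and both ends lie many standard errors from 0.

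By list, 8 of 20 passed for committing against uncommitted cells at limma's camera with its preset correlation, and none of them did with an estimated correlation. With fry the adjusted p was 0.00123 for Wnt targets, 0.00597 for the BMP and TGF-beta response and for oxidative phosphorylation, 0.0166 for Notch, 0.0172 for S phase, 0.0312 for immediate early genes, 0.0501 for G2 and M phase and 0.174 for ribosomal proteins. Canonical Wnt targets were higher (adjusted p = 0.00264; adjusted p = 0.348 with an estimated correlation): 5 of 8 measured members rose, Sp5, Lef1, Tcf7 (0.996 ± 0.20), Nkd1 (0.96 ± 0.12) and Wls (0.36 ± 0.12), and Tcf7l2 fell by 0.41 ± 0.09. Tcf7 encodes a further partner of beta-catenin, Nkd1 a feedback inhibitor of the pathway and Wls the carrier that Wnt proteins need for secretion. Of the BMP and TGF-beta response, 9 of 15 members rose and 4 fell (camera adjusted p = 0.00443; adjusted p = 0.348 with an estimated correlation). Id1 and Id2 rose, while the ligand gene Bmp7, which sustains progenitors, fell by 1.04 ± 0.07, from 165 ± 31.3 to 79.5 ± 12.8 CPM. The matrix gene Tgfbi fell by 0.95 ± 0.05 and the ligand genes Bmp4 and Tgfb2 by 0.43 ± 0.16 and 0.52 ± 0.19. Without the library block the list's camera adjusted p was 0.051. The Notch pathway was lower (camera adjusted p = 0.0265; adjusted p = 0.348 with an estimated correlation), with 6 of 10 members lower. Hes1, a target gene of Notch receptors, fell by 0.50 ± 0.05, from 509 ± 92 to 361 ± 69.7 CPM, and Lfng fell as above. Dlk1, a Notch ligand relative expressed in immature cells, rose by 1.45 ± 0.17 and the target Hey1 by 0.65 ± 0.09. Notch2, also among the lower members, is 1 of the 85 genes at least doubled in cluster 1, whose summed level followed the cell barcode. Without the block the edgeR adjusted p of Hes1 was 0.231. Without library 2 the list's adjusted p by camera was 0.101, without the block 0.114, with cycle genes kept in the clustering 0.731, with cluster 1 left out 0.193 and with barcode-linked genes left out of the clustering 0.132. With count splitting the list was higher (camera adjusted p = 0.893). No early nephron class separated with count splitting or with cycle genes kept, and 36 and 38 of the 48 early nephron cells then counted as committing. Wls, Tcf7l2 (barcode-linked), Bmp4 and Tgfb2 were named after their values were seen. Not all held when a library was left out: the edgeR adjusted p of Wls was 0.212, 0.0983 and 0.129 without libraries 1, 2 and 3, that of Bmp4 was 0.384 without library 3, and that of Tgfb2 was 0.098 and 0.195 without libraries 1 and 3.

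Cell cycle and respiration genes were higher in committing cells. Of 52 genes of the G2 and M phase, 42 rose and 0 fell (camera adjusted p = 7.43e-18; adjusted p = 0.348 with an estimated correlation). Examples are Hmgb2 (0.53 ± 0.05), a chromatin protein, and Cdca8 (0.70 ± 0.07) and Birc5 (0.59 ± 0.06), both of the complex that guides chromosome segregation, and Cks2 (0.59 ± 0.06), a partner of cyclin-dependent kinases. Of 43 S phase genes, 28 rose and 0 fell (camera adjusted p = 7.39e-09; adjusted p = 0.348 with an estimated correlation), among them the replication inhibitor gene Gmnn (0.63 ± 0.06), Rrm2 (0.39 ± 0.05) of nucleotide reduction and Rpa2 (0.41 ± 0.06), which binds single-stranded DNA. Of 44 genes of oxidative phosphorylation, 20 rose and Ndufa6 alone fell, by 0.20 ± 0.06 (camera adjusted p = 5.55e-09; adjusted p = 0.348 with an estimated correlation). Cytochrome c (Cycs) rose by 0.41 ± 0.05, Ndufa5 of complex I by 0.38 ± 0.07, and Atp5g1 and Atp5o of the ATP synthase by 0.32 ± 0.05 and 0.26 ± 0.05. Ndufa6 was named after its value was seen, and its edgeR adjusted p was 0.0937 without library 1 and 0.0612 without library 3. Calling by edgeR over all genes gave 20 higher genes of oxidative phosphorylation, and 28 when adjusted over the list alone. The same counts were 28 and 33 for S phase and 42 and 45 for G2 and M phase. Without the library block edgeR called 0 genes of oxidative phosphorylation, 2 of S phase and 9 of G2 and M phase, and camera's adjusted p was 0.123, 4.14e-08 and 6.48e-15. Of the genes named here, only Gmnn then passed edgeR (adjusted p = 0.0245).

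Immediate early and dissociation stress genes were lower in committing cells, with 12 of 22 lower and 4 higher (camera adjusted p = 0.00011; adjusted p = 0.348 with an estimated correlation). The growth inhibitor gene Btg2 fell by 1.32 ± 0.06, from 326 ± 148 to 135 ± 80.1 CPM, and the transcription factor genes Junb, Fos and Ier2 fell by 1.12 ± 0.07, 0.77 ± 0.06 and 0.68 ± 0.05. Klf4 (0.80 ± 0.19), Klf6 (0.86 ± 0.17), Hsp90aa1 (0.20 ± 0.05) and Gadd45g (0.33 ± 0.10) rose, and were named after their values were seen. Without library 1, Klf4 had an edgeR adjusted p of 0.186, Klf6 and Hsp90aa1 had 0.0506 and 0.231 without library 3, and Gadd45g had 0.0948 and 0.586 without libraries 1 and 3. Without the library block the list's camera adjusted p was 0.051 and edgeR called 0 of its members, with adjusted p of 0.104 for Btg2, 0.3 for Junb, 0.396 for Fos and 0.555 for Ier2. These genes also differed between the libraries, as given above. Cytosolic ribosomal protein genes had a median change of -0.041 (camera adjusted p = 1.14e-06; adjusted p = 0.556 with an estimated correlation), and 79 of 82 passed no test. With barcode-linked genes left out of the clustering, the edgeR adjusted p was 0.0573 for Rps27 and 0.0593 for Gadd45g. Rps27l and Rpl7l1 had changes of 0.24 ± 0.05 and 0.17 ± 0.06 and Rps27 one of -0.14 ± 0.05, and all are of a family with many near-identical copies, so that reads can be split between them. In edgeR the adjusted p was 0.202 for Rps27l without library 3, 0.104 and 0.06 for Rps27 without libraries 1 and 3, and for Rpl7l1 0.181, 0.219 and 0.111 without libraries 1, 2 and 3.

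The other 12 lists did not pass camera for committing against uncommitted cells. Epithelial junctions and polarity had 3 of 11 members lower (adjusted p = 0.0657): Spint2 (-0.88 ± 0.12), a protease inhibitor, Tjp1 (-0.54 ± 0.15), a tight junction scaffold, and Pard3 (-0.39 ± 0.09), a polarity protein. Tjp1 had an edgeR adjusted p of 0.064 without library 1. The list's direction depended on the setting: with cycle genes kept in the clustering it was higher (camera adjusted p = 0.0042; 5 members higher, 1 lower), as it was with count splitting (adjusted p = 0.0155; 3 higher, 0 lower), both adjusted over 20 tests. In both settings most early nephron cells counted as committing, as given above, and these cells hold epithelial transcripts. Of mesenchymal genes (camera adjusted p = 0.295), 2 of 10 were higher and 4 lower. The higher ones were Snai1 (1.204 ± 0.27; edgeR adjusted p = 0.0554 without library 3) and Snai2 (0.93 ± 0.15), transcription factors that repress cadherins of epithelia. Of the FGF and ERK response (camera adjusted p = 0.176), 3 of 17 were higher and 6 lower. Spry1, a feedback inhibitor of growth factor receptors, rose by 1.37 ± 0.08, and Spred1, another inhibitor of the pathway, rose by 0.41 ± 0.13 (edgeR adjusted p = 0.401 and 0.169 without libraries 1 and 3). All 7 genes named in this paragraph were chosen after their values were seen. Guidance and migration had 3 higher and 10 lower of 21 (camera adjusted p = 0.0516), integrins and matrix 7 and 10 of 23 (0.505), and Hox genes 8 and 5 of 25 (0.354). Counts of higher and lower members were 5 and 3 of 17 for progenitor regulators (camera adjusted p = 0.516), 6 and 2 of 11 for Lin28 and Igf2bp growth genes (0.0884), 4 and 2 of 20 for glycolysis (0.926), 0 and 3 of 8 for Hippo targets (0.399), 1 and 3 of 11 for p53 targets (0.818) and 2 and 1 of 10 for the retinoid pathway (0.485).

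The next step was followed by comparing early nephron with committing cells. The early nephron class held cells with ureteric markers. In early nephron and committing cells, Calb1 was at 231 ± 302 and 0.56 ± 0.58 CPM (SD, n = 3), Gata3 at 44.7 ± 65 and 0, Ret at 9.4 ± 11.5 and 0 and Wnt11 at 8.87 ± 15.4 and 0.18 ± 0.31. Calb1 was found in 8.89% ± 10.2 and Gata3 in 12.6% ± 6.79 of early nephron cells. At least 1 UMI of the 8 ureteric markers was held by 3, 4 and 2 early nephron cells of libraries 1, 2 and 3. The sort for Six2-driven fluorescence is meant to leave out ureteric epithelium. Whether these are ureteric cells that passed the sort, doublets, or nephron cells with these transcripts was not tested. The comparison was also made without them, an alternative chosen after seeing the data. Cldn6 (ENSMUSG00000023906, chromosome 17, 23679249 to 23682446), a claudin of tight junctions in embryonic epithelia, went from 1.46 ± 0.63 to 100 ± 17.3 CPM (SD, n = 3), a log2 change of 6.05 ± 0.39 (SE), and Cldn7 from 1.29 ± 1.59 to 70.3 ± 39.5 CPM, a log2 change of 5.55 ± 0.51. Without the cells with a ureteric marker the changes were 4.72 ± 0.56 and 3.665 ± 0.77. Crb3, an apical polarity protein, had 1 UMI in all committing and 30 in all early nephron cells, a ratio of 240 per UMI sequenced with a counting interval of 39.9 to 9789.6. Of the Notch pathway, the feedback regulator gene Nrarp went from 1.67 ± 1.36 to 51 ± 37.1 CPM, a log2 change of 4.81 ± 0.50, and the receptor gene Notch1 from 1.51 ± 0.37 to 26.4 ± 9.98 CPM, a log2 change of 4.17 ± 0.53 (4.12 ± 0.58 and 4.21 ± 0.56 without the cells with a ureteric marker). Snap91, which encodes an adaptor of clathrin coats, fell by 2.29 ± 0.33, from 61.4 ± 8.3 to 11.3 ± 5.98 CPM, and Bmper by 1.97 ± 0.29.

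Of 9796 genes tested, 350 passed (edgeR, adjusted p under 0.05), 260 of them higher and 90 lower in early nephron cells. Besides Crb3, Cldn6, Cldn7 and Nrarp, the largest increases were those of Papss2, Dkk1 (5.19 ± 0.62), Grb7 (4.57 ± 0.52) and Jag1 (4.31 ± 0.45). Papss2, an enzyme that makes the sulfate donor, had 3 UMIs in committing and 19 in early nephron cells, a ratio of 50.7 with a counting interval of 14.9 to 267.3. Dkk1 encodes a secreted Wnt inhibitor and Grb7 a receptor adaptor. The Notch ligand gene Jag1 is a class marker and is no result. The largest decreases included the growth factor gene Fgf20, with 3 UMIs in early nephron and 197 in committing cells, a ratio of 8.2 with an interval of 2.8 to 40.2. Phf19 (-2.66 ± 0.51), of a chromatin-silencing complex, Lhfp (-1.57 ± 0.28), Ydjc (-1.86 ± 0.49), Snai2 (-1.71 ± 0.48) and AW551984 (-1.67 ± 0.47) completed the 8 with Snap91 and Bmper. Bmper is a class marker too. The edgeR adjusted p of these 16 genes lay between 1.13e-16 (Cldn6) and 0.0274 (AW551984), each in the same direction in 3 of 3 libraries. Jag1, Fgf20 and Lhfp belong to the genes higher in cluster 1. With the 19 genes correlated with the barcode left out of the clustering, 286 genes passed. Of these, 251 were among 339 earlier calls that were tested again. The edgeR adjusted p was then 0.102 for Ydjc, 0.127 for Snai2 and 0.124 for AW551984. The comparison rests on 48 early nephron cells, with 225395 to 482545 UMIs per library. This class too was drawn from the same cells' expression, so that genes correlated with the clustering genes pass by construction. Count splitting could not check this, since no early nephron class separated there. Without libraries 1, 2 and 3 there were 163, 239 and 181 calls, and without the block 132. Sums thinned to 206713 UMIs gave 55. Without the cells with a ureteric marker 197 genes passed, 178 of them among 313 earlier calls that were tested again. The edgeR adjusted p was then 0.164 for Snai2 and 0.109 for AW551984, and 2.14e-05 for Crb3, 0.000281 for Papss2 and 0.011 for Fgf20. Changes were 5.45 ± 0.63 for Dkk1, 4.28 ± 0.58 for Grb7, -2.36 ± 0.52 for Phf19, -2.23 ± 0.36 for Snap91, -1.49 ± 0.31 for Lhfp and -2.14 ± 0.57 for Ydjc, each past the threshold. Without the library block the edgeR adjusted p was 0.718 for Fgf20 and 0.0678 for Snai2. The edgeR adjusted p of Phf19 was 0.0918 without library 1. For Ydjc it was 0.128, 0.124 and 0.0943, for Snai2 0.302, 0.154 and 0.0795 and for AW551984 0.319, 0.0944 and 0.139 without libraries 1, 2 and 3.

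**Figure D2:**
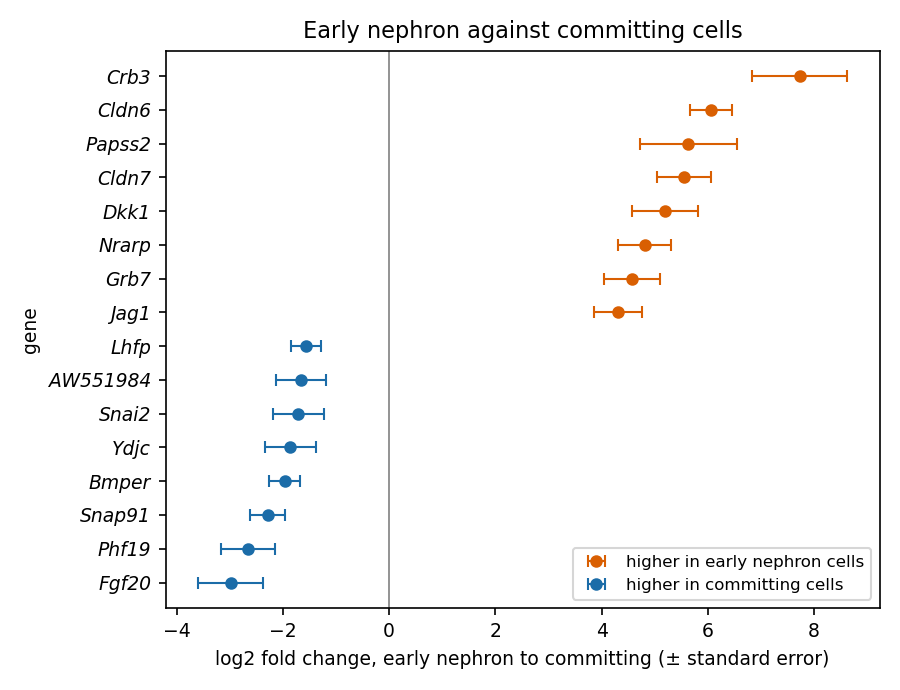
Log2 fold change (horizontal axis, log2 units, bars are standard errors) of the 16 named genes (vertical axis) between early nephron and committing cells, summed per library (n = 3). The increases are larger than the decreases, and Crb3, Papss2 and Fgf20 rest on 1 to 3 UMIs in their lower class, so that their fitted changes depend on the model's prior.

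Epithelial junctions and polarity was the list with the clearest change in early nephron cells, and the only 1 of 6 past camera that also passed with an estimated correlation (adjusted p = 8.73e-21; adjusted p = 0.0114 with an estimated correlation). Of 19 measured members 13 rose and 0 fell, 16 when adjusted over the list alone (fry adjusted p = 3.29e-05). Epcam, an epithelial adhesion molecule, rose by 4.11 ± 0.35 to 157 ± 164 CPM and Spint2 by 2.39 ± 0.22. Without the cells with a ureteric marker, 5 of 12 measured members rose and 0 fell (camera adjusted p = 1.87e-07; adjusted p = 0.0433 with an estimated correlation, both over 20 tests), with changes of 1.975 ± 0.45 for Epcam and 2.02 ± 0.25 for Spint2. The Notch pathway was higher (camera adjusted p = 4.46e-05; adjusted p = 0.0996 with an estimated correlation; fry adjusted p = 5.7e-06), with 5 of 11 members higher: Nrarp, Notch1, Lfng (3.28 ± 0.38), Hey1 (1.28 ± 0.21) and Heyl (1.45 ± 0.25). Lfng had been lower in committing than in uncommitted cells, at 5.37 ± 2.78 against 21.2 ± 4.97 CPM, and stood at 55.7 ± 46.6 CPM in early nephron cells. The earlier fall of Lfng did not pass with count splitting or with sums thinned, as given above. Without the cells with a ureteric marker the Notch list had a camera adjusted p of 0.000148, with changes of 3.23 ± 0.42 for Lfng, 1.48 ± 0.22 for Hey1 and 1.51 ± 0.29 for Heyl. The edgeR adjusted p of Hey1 was 0.0833 without library 3 and that of Heyl 0.0653 without library 1. Mesenchymal genes were lower (camera adjusted p = 0.0309; adjusted p = 0.348 with an estimated correlation), with 2 of 8 members lower, the cadherin gene Cdh11 (-1.13 ± 0.17) and Snai2. Without library 2 the list's adjusted p was 0.118, without the cells with a ureteric marker 0.201, and with barcode-linked genes left out of the clustering it was 0.0832. Hox genes were lower (camera adjusted p = 0.0141; adjusted p = 0.496 with an estimated correlation): Hoxa10 (-0.79 ± 0.11), Hoxc10 (-0.72 ± 0.13), Hoxc8 (-1.22 ± 0.28), Hoxa9 (-0.66 ± 0.18) and Hoxa11 (-0.84 ± 0.22) fell and Hoxb7 (1.02 ± 0.18) rose, of 25 members of this family of body-axis regulators. Adjusted over the list alone, 9 fell and 1 rose. With fry the adjusted p was 0.152 for mesenchymal genes, 0.443 for Hox genes, 0.159 for glycolysis and 0.0365 for ribosomal proteins. Without the library block the camera adjusted p was 0.051 for both the mesenchymal and the Hox list, and that of edgeR was 0.148 for Cdh11, 0.0892 for Hoxa10, 0.111 for Hoxc10, 0.135 for Hoxc8, 0.441 for Hoxa9 and 0.277 for Hoxa11. Without library 1 the Hox list's adjusted p was 0.0542, and the edgeR adjusted p was 0.0834 for Hoxc8 and 0.3 for Hoxa11. That of Hoxa9 was 0.0753 and 0.219 without libraries 2 and 3. Without the cells with a ureteric marker the edgeR adjusted p was 0.105 for Hoxb7, 0.36 for Hoxa9, 0.0949 for Hoxa11, and below 0.141 for Bmp7, 0.163 for Tgfbi and 0.186 for Ldha. Heyl, Hoxa9 and Hoxa11 were named after their values were seen.

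Glycolysis genes were lower by camera (adjusted p = 0.0025; adjusted p = 0.348 with an estimated correlation; 0.0655 with barcode-linked genes left out of the clustering), but only Ldha, lactate dehydrogenase, passed among 17 members (-0.28 ± 0.08). Its edgeR adjusted p was 0.395 and 0.12 without libraries 2 and 3. Cytosolic ribosomal protein genes had a median change of -0.114 (camera adjusted p = 1.19e-19; adjusted p = 0.348 with an estimated correlation), and 5 of 82 passed: Rplp0 (-0.24 ± 0.05), Rps26 (-0.30 ± 0.07), Rplp1 (-0.24 ± 0.06), Rpl21 (-0.21 ± 0.06) and, named after its value was seen, Rps15 (-0.24 ± 0.07). Adjusted over the list alone, 18 were lower and 1 was higher. Without library 1 or library 3 none of these 5 passed, with edgeR adjusted p of 0.0779 and 0.0574 for Rplp0, 0.199 and 0.16 for Rps26, 0.221 and 0.207 for Rplp1, 0.239 and 0.18 for Rpl21 and 0.363 and 0.33 for Rps15. Without library 2, Rpl21 did not pass either (0.0702). With barcode-linked genes left out of the clustering, the edgeR adjusted p was 0.168 for Ldha, 0.0675 for Rplp1, 0.139 for Rpl21, 0.115 for Rps15 and 0.799 for Tgfbi, which follows below. Of the BMP and TGF-beta response (camera adjusted p = 0.926), 4 of 14 rose and 2 fell. Bmp2 rose by 3.004 ± 0.34 to 93.8 ± 40.5 CPM, Bmp4 by 1.90 ± 0.27, the decoy receptor gene Bambi by 1.36 ± 0.26 and Bmp7 by 0.59 ± 0.16, while Id2 fell by 0.95 ± 0.12 and Tgfbi by 0.61 ± 0.14. Bambi had an edgeR adjusted p of 0.0739 without library 1, that of Bmp7 0.0826, 0.237 and 0.148 without libraries 1, 2 and 3, and that of Tgfbi 0.0813 and 0.0961 without libraries 1 and 3. Of canonical Wnt targets (camera adjusted p = 0.194), 2 of 9 rose, Dkk1 and Lef1 (1.997 ± 0.48; edgeR adjusted p = 0.138 and 0.254 without libraries 2 and 3). Without the cells with a ureteric marker the changes were 3.08 ± 0.35 for Bmp2, 1.92 ± 0.30 for Bmp4, 1.33 ± 0.28 for Bambi, -0.76 ± 0.13 for Id2 and 2.18 ± 0.50 for Lef1. The genes of these BMP and Wnt lists other than Dkk1 were named after their values were seen.

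For the remaining 12 lists no camera test passed between early nephron and committing cells. Integrins and matrix had 7 higher and 1 lower of 21 (adjusted p = 0.06), guidance and migration 3 and 1 of 21 (0.441), and the FGF and ERK response 1 and 1 of 17 (0.807). G2 and M phase genes had 3 higher and 0 lower of 52 (camera adjusted p = 0.167), S phase genes 0 and 0 of 43 (0.06) and oxidative phosphorylation 0 and 0 of 44 (0.171). Adjusted over the list alone, edgeR called 0 S phase genes as well, and over all genes at an unadjusted p under 0.05 it called 1246 genes for this comparison. Counts were 1 and 0 of 21 for immediate early genes (camera adjusted p = 0.973), 1 and 2 of 17 for progenitor regulators (0.085), 0 and 1 of 11 for Lin28 and Igf2bp growth genes (0.152), 1 and 0 of 8 for Hippo targets (0.142), 0 and 0 of 11 for p53 targets (0.818) and 2 and 1 of 11 for the retinoid pathway (0.799).

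Whether commitment goes with a change in cycling was also read from single cells. After thinning to 7689 UMIs per cell, transcripts of Top2a, the DNA topoisomerase of dividing cells, or of the proliferation marker Mki67 were found in 39.9% ± 3.08 of uncommitted cells (SD, n = 3), 42% ± 0.74 of Fgf8-high cells, 57.3% ± 9 of committing cells and 72.1% ± 15.8 of early nephron cells. Immune cells, which can divide as well, stood at 47.1% ± 16.4. The committing share was above the uncommitted share in each library (60.8%, 47.1% and 64% against 43.2%, 39.2% and 37.1% in libraries 1, 2 and 3), while the early nephron share of 53.8% in library 2 rested on 13 cells, with an exact interval of 25.1% to 80.8%. Without thinning the shares were 47.7%, 51.9%, 68.5% and 78.5%, at median depths of 14067.5, 15794.5, 17989 and 20964 UMIs. No test was made on cells, and with 3 pairs of libraries an exact permutation test cannot reach a two-sided p under 0.25.

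**Figure D3:**
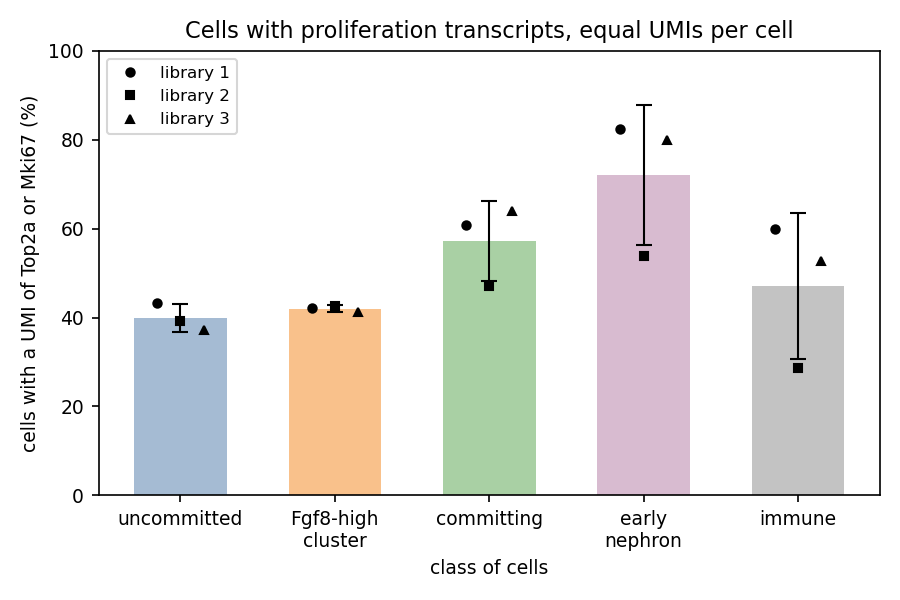
Share of cells with at least 1 UMI of Top2a or Mki67 after thinning to 7689 UMIs (vertical axis, percent) by class (horizontal axis). Bars are means over 3 libraries, error bars are SD and points are single libraries. The share in committing cells, 57.3%, lay above that in uncommitted cells, 39.9%, in all 3 libraries.

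Whether single cells hold transcripts of self-renewal and commitment together was asked from 18 gene pairs across uncommitted, committing and early nephron cells. Fgf8-high cells, 15.9% of kept cells, were left out, although both Six2 and the committing marker Pax8 were found in that cluster. The ratios below do not cover them. Six2 and Wnt4 were found together in 1.47% ± 0.251 of cells (SD, n = 3), where independence gave 1.87%, a log2 odds ratio of -0.84 ± 0.35. Cited1 and Wnt4 were found together in 1.02% ± 0.31, where independence gave 1.56%, with a ratio of -1.12 ± 0.62. Doublets of an uncommitted and a committing cell would hold both genes as well. Wnt4 went with Jag1 (4.04 ± 0.95), with Lhx1 (2.88 ± 1.06) and with Pax8, a transcription factor of the nephric lineage (1.43 ± 0.61). Among progenitor genes, Six2 went with Cited1 (0.16 ± 0.08), Osr1 (0.26 ± 0.09) and Eya1 (0.27 ± 0.14), and Cited1 with Meox1 (0.36 ± 0.09). Ratios below 0 were also seen for Cited1 and Pax8 (-0.44 ± 0.17), Cited1 and Jag1 (-0.92 ± 0.27), Cited1 and Lhx1 (-1.72 ± 1.19), Six2 and Jag1 (-1.02 ± 0.86), Six2 and Lhx1 (-2.94 ± 2.28) and Six2 and the collagen gene Col1a1 (-0.30 ± 0.10). Six2 with Pax8 (-0.20 ± 0.28), Six2 with the stromal regulator gene Foxd1 (-0.02 ± 0.28) and Six2 with Meis1 (0.14 ± 0.39) had signs that differed between libraries, and the other 15 pairs had 1 sign in all 3. In droplet data free RNA adds UMIs: in immune cells, which should lack Six2, it was found in 5.09% ± 5 of thinned cells against 63.5% ± 5.92 of uncommitted ones, and Wnt4 in 0% against 1.09% ± 0.32, at median depths before thinning of 10493 and 14407 UMIs. The log2 odds ratios cover cells of several classes and were not tested on cells.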

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

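No test was run on the values of this part, and both were singled out because they come from cells that no comparison used.

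Cluster 7, with 207 cells (2.37%, 3.05% and 2.47% of libraries 1, 2 and 3), belonged to no named class. Its barcodes held transcripts of progenitors and of stroma together. Six2 was found in 68.1% and Cited1 in 49.8% of them. The stromal collagen genes Col1a1 and Col3a1 were found in 54.6% and 47.3%, at 225 and 127 CPM, Dcn, a matrix proteoglycan, in 40.6%, Foxd1, the regulator of renal stroma, in 31.4%, and Meis1, a homeobox gene of stroma, in 70.5%. In uncommitted progenitors the same genes were found in 6.48% ± 1.12 (Col1a1; SD, n = 3), 2.73% ± 1.26 (Col3a1), 10.4% ± 1.77 (Dcn), 17.8% ± 2.86 (Foxd1) and 61.4% ± 1.81 (Meis1) of cells, and in immune cells in 5.44% ± 4.72, 1.39% ± 2.41, 1.39% ± 2.41, 4.17% ± 4.17 and 11% ± 2.6, so that Meis1 marks stroma poorly here. Doublets have to be taken as still present in these data. Droplets of a progenitor and a stromal cell, free RNA and cells that make both sets were not separated. The median depth of these cells was 14432 UMIs, against 14067.5 in uncommitted and 9468 in immune cells.

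Of 5844 uncommitted progenitors, 380 (6.5%) held UMIs of both Xist, which silences 1 X chromosome in female cells, and of a Y gene, and were left out of the comparison of the sexes. The share was 8.47%, 4.39% and 6.43% in libraries 1, 2 and 3. Each library held cells of both sexes, so droplets with cells of 2 embryos and free RNA would each put both transcripts into 1 barcode. These sources were not separated.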

How the results depend on the processing

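Tests chosen only after results were seen were clustering as planned without library centring, clustering with cycle genes kept, removal of the 6% highest doublet scores, leaving out cluster 1, adding the Fgf8-high cluster to the uncommitted class, adding early nephron cells to the fit, leaving out early nephron cells with a ureteric marker, thinning only the compared sums, and clustering without barcode-linked genes. Of changes not explained by how an alternative was built, the cause was not tested.

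Class shares moved with the clustering, mostly because cells changed between the uncommitted and Fgf8-high classes. Uncommitted progenitors took 98.1% of cells without centring, 91.7% with cycle genes kept, 87.8% with 2000 variable genes, 91.1% and 78.7% at resolutions of 0.5 and 1.2, 75.8% with doublets kept, 90.1% with the 6% filter or with the Fgf8-high cluster added, 94.8% with count splitting, 88.8% without barcode-linked genes and 67% with cluster 1 left out. Fgf8-high cells took 11.9% at resolution 1.2, 14.4% with doublets kept, 14.8% at 5% mitochondrial UMIs at most and 20.4% with cluster 1 left out. Near-equal shares hid other members: of 1242 Fgf8-high cells, 806, 721 and 583 stayed so in the first 3 of these. Of 437 committing cells, 284 stayed with cycle genes kept, 337 with 2000 variable genes and 149 with count splitting. Committing cells took 6.12% with cycle genes kept, 8.82% with 2000 variable genes, 5.02% and 5.11% at the 2 resolutions, 6.16% with the 6% filter, 6.53% at 5% mitochondrial UMIs, 2.63% with count splitting and 7.17% with cluster 1 left out. Early nephron cells took 0.826% without barcode-linked genes and 0.794% with cluster 1 left out, and immune cells 0.72% at 5% mitochondrial UMIs and 1.22% with cluster 1 left out. The Fgf8-high cluster did not separate under 7 clusterings. Without centring no committing class separated, and no early nephron class separated without centring, with cycle genes kept or with count splitting.

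For committing against uncommitted cells, 2317 calls became 671 with DESeq2's Wald test, 497 without the block, 1489 with 2000 variable genes, 1338 with count splitting, 65 with all sums thinned to equal totals, 1154 with only the compared sums thinned and 1125 to 2481 with a library left out. Lists past camera fell from 8 to 3 without the block and to 0 with an estimated correlation, against 7 to 9 with a library left out. For early nephron against committing cells, 350 calls became 132 without the block, 55 when thinned, 197 without the cells with a ureteric marker and 163 to 239 with a library left out, and 1 list passed with an estimated correlation. Between the sexes, 57 calls became 12 with DESeq2's Wald test, 42 to 59 with a library left out and 0 in edgeR without the block (201 at an unadjusted p under 0.05). Lists then fell from 7 to 2 without the block, to 4 to 6 with a library left out and to 0 with an estimated correlation. Thinning lowers counts by construction, and counts set the limit of detection in the smaller classes.

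A few values changed sign. Against uncommitted cells the Notch list was higher with count splitting (camera adjusted p = 0.893), the epithelial list was higher with cycle genes kept (0.0042) and with count splitting (0.0155), and the glycolysis list was lower with count splitting (0.0456). With sums thinned, the log2 changes were -0.007 for Rpl7l1, 0.078 for Tcf7l2 and -0.57 for Klf6, and Bmp4 stood at 0.45 with count splitting and 0.043 with cycle genes kept. Between the sexes the G2 and M phase list was lower without library 2 (camera adjusted p = 0.991; 1.36e-07, higher, without library 3). With such changes counted in, values for lists past camera were on the same side of the threshold in 62 of 80, 36 of 48 and 33 of 56 cases for the 3 comparisons in the order above. For named genes this held in 1084 of 1240, 548 of 660 and 163 of 220 cases, and for gene pairs 92 of 108 values moved by less than their spread.

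Cycling shares moved with the thinning depth and in the setting with doublets kept: uncommitted cells stood at 48.6% when thinned to the 20th percentile (10880 UMIs) and 47.7% unthinned, Fgf8-high cells at 51.6%, 51.9% and, with doublets kept, 51.2%, and committing cells at 68.5% unthinned. With doublets kept the cells were clustered anew, and 721 of the 1242 Fgf8-high cells stayed in that class. Its share there covers other cells and is not an effect of the added doublets alone. A planned comparison of stroma-like cells was not run, since no cluster was named stroma.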

Other observations

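The comparisons of clusters, the length and class tests of the ribosomal share, the depth test of cluster 1 and the regrouping of libraries were chosen only after results were seen. Uncommitted progenitors were not uniform. Cluster 0 (1910 cells) held more Stc1, the hormone stanniocalcin, with a log2 change of 1.14 ± 0.06 (SE) against the mean of the other uncommitted clusters. Its level was 121 ± 10.6 against 57.7 ± 18.3 CPM (SD, n = 3). Efemp1 (1.09 ± 0.09), Colec12 (0.88 ± 0.05) and Dcx (0.79 ± 0.07) were higher as well. These genes and Stc1 were lower in committing than in uncommitted cells. Cluster 0 also held more Bmp4 (0.94 ± 0.08) and Zeb2 (0.86 ± 0.07), a repressor of epithelial genes. Pax8 was lower there (-0.88 ± 0.09). Of its lists, guidance and migration was higher in 10 of 24 genes and lower in 1 (camera adjusted p = 1.99e-05; adjusted p = 0.00723 with an estimated correlation), and oxidative phosphorylation was lower in 27 of 44 and higher in 1 (camera adjusted p = 7.43e-12; adjusted p = 0.00723 with an estimated correlation). Immediate early genes were higher there in 12 of 22 and lower in 1 (camera adjusted p = 8.62e-06; adjusted p = 0.124 with an estimated correlation). Cluster 4 (909 cells) went the other way: oxidative phosphorylation was higher in 39 of 44 genes and lower in 0 (camera adjusted p = 1.07e-36; adjusted p = 3.8e-05 with an estimated correlation), and guidance and migration lower in 9 of 24 and higher in 1 (camera adjusted p = 6.85e-05; adjusted p = 0.00773 with an estimated correlation). Immediate early genes were lower in 13 of 22 and higher in 1, with a median change of -0.519 (camera adjusted p = 5.8e-09; adjusted p = 0.0332 with an estimated correlation). Dissociation acts on these genes, and its part was not separated. In cluster 0 cell cycle lists were lower: S phase in 33 of 43 genes and higher in 0 (camera adjusted p = 4.87e-19, and 0.114 with an estimated correlation). G2 and M phase genes were lower there in 27 of 52 and higher in 0 (camera adjusted p = 2.52e-09, and 0.426 with an estimated correlation). Cluster 4 had members both ways. Its S phase genes were lower in 12 of 43 and higher in 2 (camera adjusted p = 0.0116, and 0.62 with an estimated correlation). Its G2 and M phase genes were lower in 26 of 52 and higher in 8 (camera adjusted p = 4.99e-05, and 0.553 with an estimated correlation). Of these, Ccnb2 was higher (0.845 ± 0.078), as was the barcode-linked Cenpa (0.64 ± 0.06), while Nusap1 was lower (-1.12 ± 0.12). Each cluster was compared with a mean that contains the other, so opposite signs are partly built in. In cluster 4 Hist1h2bc, a histone gene whose transcript can carry a poly(A) tail, was higher by 1.55 ± 0.07. The imprinted growth regulator H19 was higher by 0.65 ± 0.04, while Dcx (-1.68 ± 0.10) and Colec12 (-1.41 ± 0.08) were lower there. The committing marker Pax8 was also higher in cluster 4 (0.76 ± 0.09), as was Wfdc2 (0.86 ± 0.10), which was higher in committing than in uncommitted cells. Epcam was among the leading genes of cluster 4.

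The Fgf8-high cluster held more Pax8 (0.93 ± 0.07, a marker that named it), Fgf20 (0.76 ± 0.07) and the proto-oncogene Mycn (0.66 ± 0.06), both barcode-linked, the retinoic acid enzyme Aldh1a2 (0.65 ± 0.06) and Gdnf (0.51 ± 0.05), the signal that makes the ureteric bud branch, and less Zeb2 (-1.03 ± 0.10), Stc1 (-0.73 ± 0.07) and Rspo3 (-0.65 ± 0.05), which strengthens Wnt signals. G2 and M phase genes were higher in 34 of 52 and lower in 0 (camera adjusted p = 2.56e-17; adjusted p = 0.249 with an estimated correlation). Cluster 3 (925 cells; 8.39%, 15.8% and 11.3% of libraries 1, 2 and 3) held more immediate early genes, with 13 of 22 higher and 0 lower (camera adjusted p = 7.19e-19; adjusted p = 0.00653 with an estimated correlation), among them Fosb (0.84 ± 0.07), and more Cyr61 (0.87 ± 0.08), a matrix gene induced by stretch, and Top2a (0.78 ± 0.07). Oxidative phosphorylation was lower there in 10 of 44 genes and higher in 1 (camera adjusted p = 1.99e-08; adjusted p = 0.0157 with an estimated correlation), and epithelial junctions and polarity lower in 4 of 13 and higher in 0 (adjusted p = 0.000333 and 0.0261). G2 and M phase genes were higher in 37 of 52 (camera adjusted p = 2.56e-26; adjusted p = 0.151 with an estimated correlation) and S phase genes in 22 of 43 (adjusted p = 1.15e-16 and 0.147). Dissociation induces the same early genes, and cluster 3 was largest in library 2, where they were highest. In cluster 6 (353 cells) H2-DMa, of the machinery that loads class II antigens, was higher by 1.49 ± 0.17 and Hist1h2bc lower (-0.89 ± 0.12); other class II genes defined this cluster. Oxidative phosphorylation was lower there in 2 of 44 genes and higher in 0 (camera adjusted p = 9.01e-07; adjusted p = 0.0332 with an estimated correlation). Calls in edgeR were 2248 for cluster 0, 1194 for the Fgf8-high cluster, 844 for cluster 3, 2352 for cluster 4 and 71 for cluster 6, of 11311 genes. Clusters were drawn from the same expression values, so that genes correlated with the clustering genes pass by construction, no library was left out in these tests, and without barcode-linked genes the Fgf8-high cluster did not separate.

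Female and male progenitors of the uncommitted class, 2646 and 2525 cells, differed little outside the sex chromosomes. Of 12495 genes 57 passed (edgeR, adjusted p under 0.05), 39 higher and 18 lower in female cells: 10 on X (8 higher), 2 on Y and 45 elsewhere (31 higher), of which Runx1t1 alone changed at least 2-fold (1.40 ± 0.34; named after its value was seen; edgeR adjusted p = 0.238 and 0.43 without libraries 2 and 3). The X genes Eif2s3x (0.61 ± 0.05), Pbdc1 (0.51 ± 0.03) and Kdm5c (0.49 ± 0.06) were higher in female cells. Eif2s3x and Kdm5c, a translation factor and a histone demethylase, are known to escape X inactivation. Mid1 (-1.53 ± 0.09), which spans the boundary of the region that X and Y share, and Erdr1 (-1.52 ± 0.10) were lower, and Gm29650 on Y had 1 UMI in female and 51 in male cells, a ratio of 55.1 with a counting interval of 9.5 to 2219.8. Among the other genes with the smallest p, the imprinted cell cycle inhibitor gene Cdkn1c was higher by 0.19 ± 0.02 (2105 ± 381 against 1842 ± 359 CPM) and Phlda1 by 0.26 ± 0.03, and Hist1h2bc (-0.33 ± 0.04) and Cited1 on X (-0.22 ± 0.03; 175 ± 18.3 against 205 ± 34.3 CPM) were lower. All 10 genes had the same direction in 3 of 3 libraries, and none passed without the library block (0 calls in edgeR, 201 at an unadjusted p under 0.05). With barcode-linked genes left out of the clustering 48 genes passed, 40 of them among the 57, and Runx1t1 had an edgeR adjusted p of 0.283. Female cells made up 58.4% (exact interval 56.2% to 60.6%), 35.7% (33.5% to 38%) and 61.5% (58.9% to 64.1%) of cells of 1 sex in libraries 1, 2 and 3.

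Glycolysis genes were lower in female cells (camera adjusted p = 7.34e-16; adjusted p = 0.235 with an estimated correlation), with a median change of -0.085 and a fry adjusted p of 0.0172; the fry adjusted p of the other 6 lists past camera was 0.0922 or higher. Of 20 members 6 fell and 0 rose, 7 when adjusted over the list alone: Ldha (-0.14 ± 0.02), Tpi1 (-0.12 ± 0.02), Aldoa (-0.11 ± 0.02), Eno1 (-0.09 ± 0.02), Pgam1 (-0.08 ± 0.02) and Pkm (-0.07 ± 0.02), enzymes that turn glucose into lactate, named after their values were seen. In edgeR the adjusted p without library 2 was 0.512 for Eno1 and 0.542 for Pgam1 and Pkm, without library 3 it was 0.0882 for Pgam1 and 0.229 for Pkm, and without library 1 it was 0.0529 for Pgam1. Cluster 4, where 9 of 20 glycolysis genes were higher and 1 lower, held 13.8% ± 3.31 of female and 17.3% ± 3.07 of male cells (SD, n = 3). Its share was lower in female cells in each library. The glycolysis list was not tested with the makeup of clusters held equal. S phase genes (median 0.034; camera adjusted p = 0.00011; adjusted p = 0.556 with an estimated correlation), guidance and migration (0.033; adjusted p = 0.0147 and 0.348) and Hippo targets (0.047; adjusted p = 0.0309 and 0.348) were higher. Of Hippo targets 1 of 8 passed edgeR, the matrix gene Cyr61 (0.21 ± 0.03), and of 52 G2 and M phase genes 2 passed, Top2a (0.12 ± 0.03) and Cenpe (0.17 ± 0.04), a kinesin of chromosomes (median of the list 0.015; camera adjusted p = 0.0242; adjusted p = 0.72 with an estimated correlation). These 3 genes were named after their values were seen, and edgeR's adjusted p without libraries 1 and 2 was 0.474 and 0.597 for Top2a and without library 2 it was 0.364 for Cenpe. With barcode-linked genes left out of the clustering, edgeR's adjusted p was 0.652 for Top2a, 0.109 for Cenpe, 0.138 for Eno1 and 0.279 for Pkm, and camera's adjusted p was 0.377 for the G2 and M phase list. Oxidative phosphorylation (median -0.023; camera adjusted p = 3.93e-05; adjusted p = 0.515 with an estimated correlation) and cytosolic ribosomal proteins (median -0.017; adjusted p = 2.35e-19 and 0.496) were lower, with 0 single genes past edgeR in both, against 924 of all genes at an unadjusted p under 0.05 and 12 called by DESeq2. Without library 1 camera's adjusted p was 0.247 for oxidative phosphorylation, 0.895 for S phase, 0.432 for G2 and M phase and 0.903 for ribosomal proteins. It was 0.132 and 0.0599 for guidance and migration and 0.126 and 0.104 for Hippo targets without libraries 2 and 3, and 0.991 for G2 and M phase without library 2. The other 13 lists did not pass, with camera adjusted p between 0.085 for Lin28 and Igf2bp growth genes and 0.926 for the FGF and ERK response.

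The lower Cited1 and higher Cdkn1c of female cells may be a biological difference of the sexes, which is a hypothesis. With sums per cluster and sex, so that the makeup of clusters was held equal, the smaller of the 2 changes was 0.91 of the original, and with depth made equal it was 0.95, so for these 2 genes the tests argue against a different makeup of clusters and against depth as the cause. Calls in edgeR fell from 57 to 28 (17 higher) and 26 (16 higher) in the same fits, so this does not extend to all 57 genes. The fit by cluster had 30 sums, with a block for each cluster and library. Clusters of 1 tube thus counted as separate pairs, although they are not independent, and its calls cannot be set directly against those from 6 sums. The sexes share every tube, and what else differs between their embryos was not given.

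Cluster 1 (1747 cells), which held 284 higher and 15 lower genes such as Spry2 (2.98 ± 0.10) and Notch2 (2.85 ± 0.09), may come from priming that depends on the cell barcode. Its canonical Wnt targets were higher in 2 of 8 genes and lower in 0 (camera adjusted p = 0.000164; adjusted p = 0.0216 with an estimated correlation) and its FGF and ERK response in 3 of 17 and lower in 0 (adjusted p = 0.000273 and 0.0157), so the pattern reaches lists that other comparisons test. Its cells had other barcode bases (largest Cramer's V 0.211 over 16 positions, against 0.054 to 0.064 in other clusters; 57.5% A and T against 46.6%), and the level of its 85 doubled genes rose with the A and T bases of the barcode in uncommitted cells, from 3296 to 4265 and 8408 CPM at up to 6, 7 to 9 and 10 or more such bases, and in immune cells, from 5948 to 8605 and 14587 CPM (6 cells in the last). A sequence shared by the transcripts was found as well. TTTTTTTTTT was found in 80.8% of the 308 higher genes (the 284 and those used for clustering) and 30.1% of genes of equal length. This was an excess of 50.8 points against 6.9 at most in 100 random draws. The sequence was sought on the strand of the transcript, and whether priming acts at it was not tested. Median depth relative to other uncommitted cells was 0.831 to 1.039, and 4235 longer genes had a median change of 0.009. The mean correlation was 0.138 at least in the libraries not used to pick the genes, against 0.0201 at most in random lists. These values argue against depth, transcript length and chance co-variation as causes. Doublet scores had a ratio of 1.067 at most. Doublets have to be taken as still present, so these scores cannot decide on doublets as a cause. No biological explanation was tested.

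No cause tested here accounted for the lower ribosomal protein share of library 2. In uncommitted cells the share of library 2 was 0.581 of the mean of the others, and 0.581 in female uncommitted cells, so a different makeup of classes or of sexes would not account for it. The shortest 20% of other genes had a median log2 ratio of 0.104 in library 2 and the longest 20% one of 0.139, which argues against a loss of short transcripts. The ratio lay between 0.541 (immune cells) and 0.598 (committing cells) in every class examined. A biological explanation was not tested, since the labels put all tubes in 1 group.

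For each comparison the 6 sums were regrouped into all 10 splits of 3 against 3, which are too few for a share under 0.05. In each case 1 of the 10 splits, the real one itself, gave as many edgeR calls: 2317 for committing against uncommitted cells (highest other 0; at an unadjusted p under 0.05, 3353 against 421), 350 for early nephron against committing cells (highest other 0; 1246 against 266) and 57 between the sexes (highest other 7; 924 against 721). Among the 4 splits that part the 2 sums of every library, the real one included, the highest other was 0, and the remaining splits put both sums of a library into 1 group. For the 2 comparisons of classes, the classes were drawn from the same expression values. The real split then gives the most calls by construction, and the regrouping cannot speak to chance there.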
